A study of Mus musculus with 14 samples.

How the data were processed

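The samples were 14 RNA libraries of mouse E14 embryonic stem cells, 6 of WT cells and 8 of Mettl3-KO cells. Mettl3 is the catalytic subunit of the methyltransferase that writes m6A on mRNA. Per the labels' protocols, the cells were held for 2 weeks with 200 nM INK128, an inhibitor of the mTOR kinase that brings embryonic stem cells into a paused state. They were then given 100 µM S4U, a thiolated uridine that cells build into new RNA, for 12 h, with fresh medium every 3 h. After a return to medium without S4U they were collected at 0, 1, 3 and 8 h. Per the labels' protocols, RNA was treated with 10 mM iodoacetamide, which makes S4U read as C, and 3' end libraries were made from 100 ng of RNA. WT has 1 library at 0 h, 2 at 1 h, 1 at 3 h and 2 at 8 h, and Mettl3-KO has 2 at each time. Groups and replicate numbers were taken from the titles in the labels. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

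The authors deposited 2 tables of whole-number counts per gene, the total count and the count of T>C conversions, each with 36336 entries named by gene symbol. The submitters' processing notes name Trim Galore 0.4.0, featureCounts of Subread 1.5.0, edgeR 3.32.1 and the genome build mm10. Which step made which table, the aligner and the calling of conversions are not given in the sources used here, nor is whether a conversion count is a read or a converted base. For 152 genes a library holds more conversion counts than total counts, and 34 of these genes entered the tests. Another deposited table holds log2 values normalized by the authors for 17164 genes. Their antilogs, with each library's own scale taken out, were divided by the deposited counts. With a tolerance of 1%, this showed which further multiple of the count each library carries. A last deposited table holds other values, half-lives and correlations fitted by the authors for 6985 genes, with no unit in its header. The values from these last 2 tables are named as the authors' wherever they appear.

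Total RNA was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests with robust dispersion and TMM scaling, on genes with at least 10 counts in at least 6 libraries. The model held chase time as a factor and genotype, and 14641 genes were tested. A second model with hours and their interaction with genotype tested whether total RNA moved differently over the chase. Conversion counts were tested in the same way on 12678 genes with at least 10 conversion counts in at least 3 libraries. Their library scale was the TMM-scaled total count of the same library, so that values are labelled RNA per unit of total RNA. The model of genotype, hours and their interaction gave the difference at 0 h, the loss of label per hour in each genotype and the difference in loss rate. A loss rate difference above 0 means slower loss in Mettl3-KO. Half-lives are the hours in which the fitted label falls by 50%, with no correction for cell division. Standard errors are the log2 effect divided by the square root of its F statistic. Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM values use TMM-scaled totals. All 14 libraries shared each fit, since WT at 0 h and at 3 h has 1 library each and the lone library is assumed to vary like the others. The 1 entry without a gene name was left out of library sizes and tests. It held between 0.00707% and 0.0312% of the total counts of a library.

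The slope of each library's labelled share over hours was compared between genotypes with a two-sided exact permutation test over all 324 assignments of genotype within chase time. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists. The lists were m6A writers, readers and erasers, mRNAs described as m6A-methylated, pluripotency factors, primed epiblast markers, the MYC family, MYC target and ribosome biogenesis genes, ribosomal proteins, oxidative phosphorylation, glycolysis, ATF4 targets, p53 targets, cholesterol biosynthesis, lysosome and autophagy, immediate early genes, mRNA decay factors, DNA replication and G1/S, mitosis, 2-cell-like, endoderm, mesoderm and trophoblast, neural and fibroblast markers, and Zfp genes. Lists, tests, groups and the rule for named genes were set before the data were examined. The rule names Mettl3, the 8 genes with the smallest p per direction for total RNA (with a log2 change of at least 1) and for the loss rate, the 5 per direction for labelled RNA at 0 h (all past the threshold), up to 4 members of each list per comparison, and Mycn, Myc, Nanog, Klf4, Sox2 and Pou5f1. Other genes named below were chosen after their values were seen. Gene positions are from RefSeq on GRCm38.p6, the assembly of mm10.

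The tests were tried on simulated counts drawn from the real means, library sizes and dispersions, with each gene drawn independently of the others. For total RNA 20% of 100 genes changed by log2 1 and 73% of 100 changed by log2 2 were recovered, with 2 unchanged genes called among 14191. For the loss rate 5% of 100 genes changed by 0.25 log2 per hour and 39% of 100 changed by 0.5 were recovered, with 7 unchanged genes called among 12238. There all unchanged genes shared the same slope in both genotypes, with no difference at 0 h. The low labelled shares of WT 1 h replicate 2 and Mettl3-KO 3 h replicate 2 were not simulated. The count of 7 therefore does not bound the false calls in the real data. Total counts ranged from 6108570 to 26656352 in 12 libraries. WT 1 h replicate 2 held 49159 total counts and Mettl3-KO 3 h replicate 2 held 602485. Labelled shares of single libraries carry 95% Clopper-Pearson intervals, and a count of 3 is the upper limit that 0 counts allow; both cover counting error only. Replicates of each group differed well beyond sampling noise, with chi-square per degree of freedom between 10.2 and 440, so none was merged.

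Alternatives set in advance were RLE scaling, DESeq2 1.42.0, no filter and stricter filters, the replicate number as a term, fewer chase times, time as a factor, other library scales for the conversion counts and each library left out in turn. Chosen after seeing the data were fits without the 2 shallow libraries, without genes of high labelled share at 8 h or with more conversion than total counts, and limma on the authors' normalized values with and without their library multiples. For the gene list tests the replicate term was also chosen then. Regroupings of the libraries numbered 100 per test. Some single-gene results are not reported here.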

Results

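Labelled and total RNA were counted per gene in paused mouse embryonic stem cells, WT (6 libraries) and Mettl3-KO (8 libraries), at 0, 1, 3 and 8 h after removal of S4U. The design asks how RNA levels and mRNA stability differ without Mettl3 in the paused state. Total counts were between 6108570 and 26656352 in 12 libraries. They were far lower in WT 1 h replicate 2 (49159) and Mettl3-KO 3 h replicate 2 (602485).

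Mettl3 (chromosome 14, 52294841 to 52308741) was lower in Mettl3-KO libraries, at 2.16 CPM ± 1.45 (SD, n = 8) against 40.4 ± 20.7 (SD, n = 6) in WT. The log2 change was -4.63 (SE 0.29, edgeR adjusted p = 3.89e-07). The 7 deep Mettl3-KO libraries held between 14 and 55 Mettl3 counts. The 5 deep WT libraries held between 151 and 783. Mettl3-KO 3 h replicate 2 had 2 counts (5.59 CPM) and WT 1 h replicate 2 had 1 count (20.3 CPM), so the gene does not check the label of WT 1 h replicate 2. The level in Mettl3-KO 3 h replicate 2 lies below the 23.0 CPM of the lowest deep WT library.

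In Mettl3-KO libraries, total RNA of the pluripotency regulators Klf5, Tfcp2l1 and Tbx3 was lower while Mycn and 2 members of the same pluripotency list, Dppa3 and Klf2, were higher. Klf5, a Krüppel-like factor of the naive network, had 426 CPM ± 231 (SD, n = 8) in Mettl3-KO and 7811 ± 3752 (SD, n = 6) in WT, a log2 change of -4.30 (SE 0.44). Tfcp2l1, another naive regulator, fell by 2.71 on the log2 scale (SE 0.25) and Tbx3 by 2.26 (SE 0.43). Dppa3 rose by 3.73 (SE 0.39) and Klf2, a Krüppel-like factor, by 0.93 (SE 0.29). Mycn (chromosome 12, 12936093 to 12941836), a MYC family transcription factor, rose by 1.98 (SE 0.26, edgeR adjusted p = 0.000137), from 120 CPM ± 71.3 (SD, n = 6) to 424 ± 109 (SD, n = 8).

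**Figure D1:**
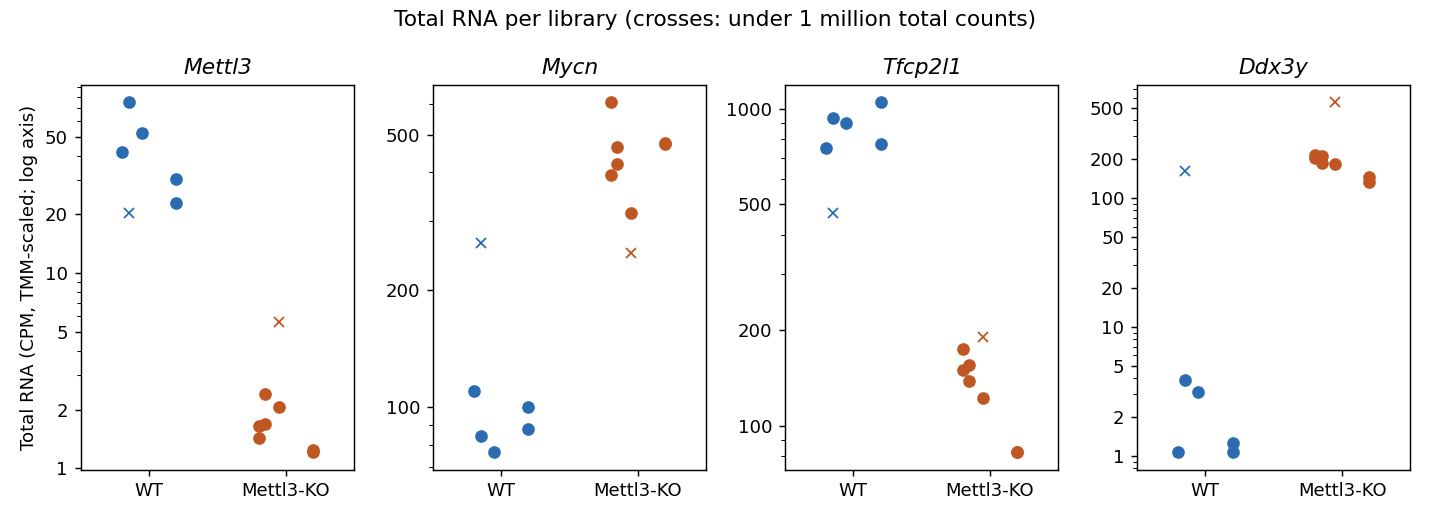
Total RNA of Mettl3, Mycn, Tfcp2l1 and Ddx3y in each library (CPM, log axis; blue WT, orange Mettl3-KO, shifted slightly by chase time; crosses are the 2 shallow libraries). WT 1 h replicate 2 has Mycn at 263.8 CPM, above the other WT libraries, which lie between 76.5 and 109.7.

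In all, 1769 genes were higher and 1462 lower in Mettl3-KO among 14641 tested, and 1370 and 1155 of these changed by at least 1 on the log2 scale. The smallest p-values of higher genes belonged to Pnp2, Bnipl, Fmr1nb, Igfbp2, Kitl, Uty, Cyyr1 and Zic5. Igfbp2, an IGF-binding protein, had 153 CPM ± 39.6 (SD, n = 8) against 19.02 ± 10.8 (SD, n = 6). Kitl, the ligand of the Kit receptor, had 22.7 ± 5.06 against 1.05 ± 0.66. Among lower genes they belonged to Sult5a1, Mettl3, Slc13a5, Emp2, Wnt6, Msln, Islr2 and Synpo2l. Wnt6, a Wnt ligand, had 1.62 CPM ± 0.68 against 33.6 ± 17.2, and Islr2 had 3.93 ± 4.09 against 91.2 ± 36.9. The lines differ in more than Mettl3, since Y-linked Uty and Eif2s3y stood at 0.866% and 0.838% of their Mettl3-KO level in deep WT libraries, so these changes cannot be credited to Mettl3 alone. Without the 2 shallow libraries the counts were 3189 and 2812, of which 1762 and 1460 were called in all 14 libraries too. Without Mettl3-KO 3 h replicate 2 alone they were 2800 and 2481, and without WT 1 h replicate 1 there were 953 lower genes. DESeq2 called 2358 lower genes, and with no count filter there were 1097 higher and 973 lower.

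Endoderm markers were lower as a group in total RNA. Of 17 measured, 8 fell, 1 rose and 8 did not pass, with a median log2 change of -1.44 (9 fell and 1 rose when adjusted over the list alone). Gata4, a primitive endoderm transcription factor, fell by 3.55 (SE 0.47), Sox7 by 3.50 (SE 0.47), Lama1, a basement membrane laminin, by 2.88 (SE 0.27) and Srgn by 5.30 (SE 0.59). The member that rose was Foxa2 (1.86). The camera adjusted p was 9.00e-07 with a preset correlation of 0.01, and the call was lost at adjusted p = 0.186 with an estimated correlation.

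Primed epiblast markers were higher as a group. Of 13 measured, 10 lay above 0 and 8 were called higher (9 when adjusted over the list alone), with a median of 1.53. Zic2 rose by 5.01 (SE 0.57), Sox3 by 2.88 (SE 0.49), Sox4 by 1.91 (SE 0.27) and Dnmt3b, a de novo DNA methyltransferase, by 1.06 (SE 0.21). The camera adjusted p was 0.000435 with the preset correlation (adjusted p = 0.186 with an estimated correlation). Among 26 pluripotency factors 7 fell and 2 rose (8 and 2 when adjusted over the list alone). Those that did not pass include Nanog (-0.21, SE 0.20), Sox2 (0.03, SE 0.28), Klf4 (0.11, SE 0.25) and Pou5f1 (0.05, SE 0.26). That list had no camera call (adjusted p = 0.0846, and adjusted p = 0.813 with an estimated correlation). Without the 2 shallow libraries it was called downward (adjusted p = 0.0263).

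Immediate early and growth factor response genes were lower as a group. Of 23 measured, 10 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of -0.62. Spry2 fell by 2.11 (SE 0.26), Junb by 2.04 (SE 0.35), Dusp1 by 1.90 (SE 0.31) and Dusp6, a phosphatase of ERK, by 1.64 (SE 0.32), and Dusp4 rose by 1.23. The camera adjusted p was 0.000435 (adjusted p = 0.567 with an estimated correlation). Of 29 lysosome and autophagy genes 9 fell and 2 rose (10 and 3 when adjusted over the list alone), with a median of -0.34. Map1lc3b, an autophagosome protein, fell by 1.74 (SE 0.26), Atp6v0d1 by 1.40 (SE 0.26) and Tfeb, a transcription factor for lysosomal genes, by 1.16 (SE 0.25). Rragd rose by 2.33 (SE 0.35) and Tfe3 by 0.69. The camera adjusted p was 0.0162 (adjusted p = 0.778 with an estimated correlation).

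The other lists had no camera call in the model of genotype and chase time over 14 libraries, and the counts in brackets are those adjusted over the list alone. Without the 2 shallow libraries MYC target genes (adjusted p = 0.0263) and neural markers (0.0150) were called upward and decay factors (0.0400) and G1/S genes (0.0437) downward. These were at adjusted p = 0.0538, 0.0680, 0.0680 and 0.0680 in 14 libraries, and at adjusted p = 0.778, 0.528, 0.778 and 0.778 with an estimated correlation. Of 19 m6A writers, readers and erasers 6 rose and 3 fell (7 and 3), among them Ythdf2 (1.53, SE 0.19) and Rbm15 (1.38, SE 0.27), both higher. Of 13 mRNAs described as m6A-methylated 2 rose, Mycn and Klf2, and Esrrb fell (2 and 1). Of 12 MYC family members Mycn rose and Mnt and Mxd1 fell (2 and 2). Of 32 MYC target and ribosome biogenesis genes 7 rose and 1 fell (7 and 1), with Ccnd2 at 3.23 (SE 0.31) and Mrto4 at 1.67 (SE 0.26). Of 31 DNA replication and G1/S genes 1 rose and 6 fell (2 and 6), with Ccnd3 at -2.68 (SE 0.28). Of 38 mRNA decay factors 5 fell (5), with Dis3, an exosome nuclease, at -1.69 (SE 0.24). Of 77 ribosomal proteins 5 rose (1), of 66 oxidative phosphorylation genes 4 rose (3), of 28 ATF4 targets 7 rose (8) and of 24 cholesterol genes Sqle rose (0).

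Of 19 glycolysis genes 3 rose and 1 fell, against 8 and 4 when adjusted over the list alone. Of 21 p53 targets 2 rose and 2 fell (2 and 2 over the list alone), and of 28 mitosis genes Birc5 rose and Cenpf fell (1 and 1). Among markers of other cell types, Kdr, Tfap2c and Rhox6 rose and T fell of 15 mesoderm and trophoblast genes (3 and 2). Of 8 neural markers 4 rose and 1 fell (4 and 2), with Stmn2 at 4.39 (SE 0.61), Tubb3 at 3.1 (SE 0.32) and Sox1 at -2.56 (SE 0.27). Of 11 fibroblast markers Col5a2 rose and Acta2 fell (1 and 1). The 1 measured 2-cell-like marker, Zfp352, was at -1.48 (SE 0.60) and did not pass in the test over all genes (lower when adjusted over the list of 1 alone). Of 358 Zfp genes 32 rose and 29 fell (27 and 27).

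**Figure D2:**
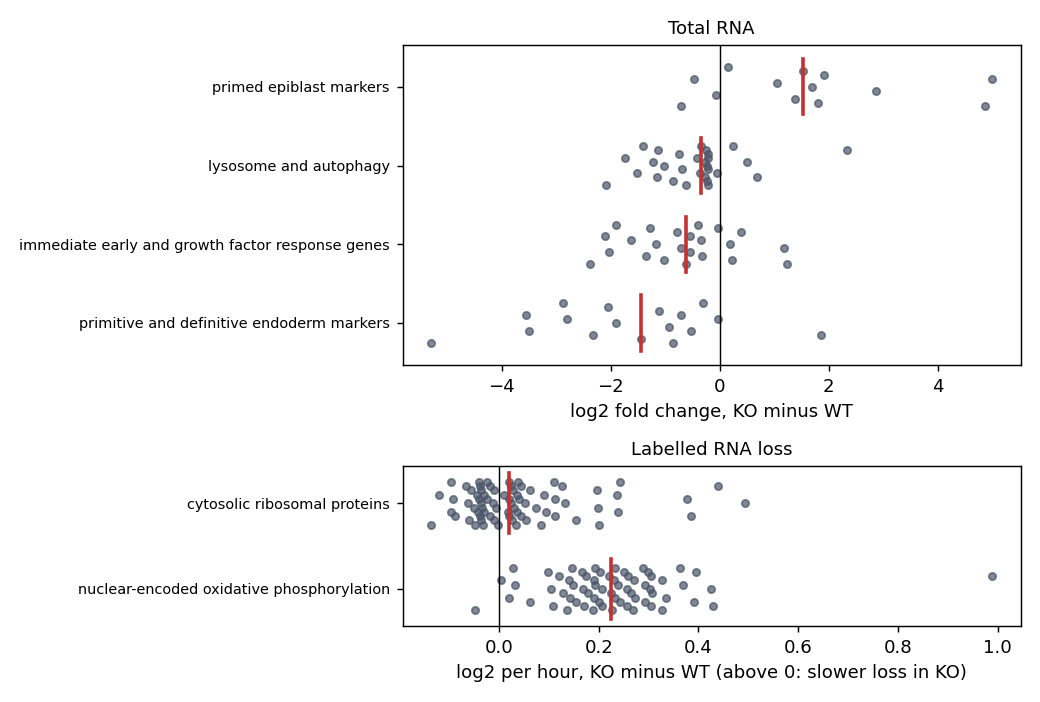
KO minus WT differences of single list members (points) with the list median (red line). The upper panel gives log2 fold changes of total RNA, and the lower panel gives differences in the loss rate of labelled RNA in log2 per hour. The oxidative phosphorylation median is 0.225 and the ribosomal protein median 0.0204 log2 per hour.

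Whether total RNA moved differently over the chase was tested by an interaction with hours. edgeR called 0 of 14641 genes, with 728 at an unadjusted p under 0.05, and DESeq2 called 197. Without the 2 shallow libraries edgeR called 80, and without Mettl3-KO 3 h replicate 2 alone it called 17.

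At the end of the pulse, a smaller share of counts carried conversions in Mettl3-KO than in WT. The labelled share at 0 h was 26.3% ± 0.34 (SD, n = 2) in Mettl3-KO and 39.4% (95% interval 39.4 to 39.5) in the 1 WT library. Fitted at 0 h over all times, labelled RNA per unit of total RNA was lower in Mettl3-KO by a median of -0.35 on the log2 scale over 12678 genes. In that test 171 genes were higher and 795 lower. Higher genes included Stmn2 (4.26, SE 0.60), Sema6a (5.18, SE 0.74), Zic5 (4.42, SE 0.65) and the Y-linked genes Ddx3y (7.47, SE 0.86) and Eif2s3y (7.95, SE 1.1). Lower genes included S100a6 (-5.34, SE 0.53), Nkx6-3 (-7.68, SE 0.74), Islr2 (-5.63, SE 0.61), Sult5a1 (-6.00, SE 0.66) and Pla2g7 (-5.10, SE 0.56).

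Nearly all of these calls were lost when each gene's own total RNA was taken out. With each gene's own total count as the offset, 0 genes were higher and 1, Dido1, lower by edgeR, and the median was -0.40. That median is over all tested genes and did not move toward 0, so it does not speak for the called genes alone. The lost calls by themselves do not show that every lower gene followed total RNA. Islr2 and Sult5a1 were also among the lower genes with the smallest p for total RNA. With the total count as the offset Mycn, at 1.71 (SE 0.53) in the test above, stood at -0.27. Stmn2, Zic5, Ythdf2, Zic2, Sox4, Ccnd2, Rragd and Tubb3 also turned from higher to below 0 without a call. Scaling the conversion counts by their own TMM factors, which removes differences across whole libraries, moved the median to 0.06 and gave 385 higher and 491 lower genes, 44.0% higher against 17.7%. The 0 h and 1 h libraries alone gave 585 higher and 1483 lower genes. Leaving out WT 1 h replicate 1 gave 77 higher and 312 lower, and leaving out Mettl3-KO 0 h replicate 1 gave 430 lower. A stricter count filter gave 108 higher genes.

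Primed epiblast markers were higher in labelled RNA at 0 h too, with 3 of 13 called and 7 when adjusted over the list alone (median 1.40, camera adjusted p = 9.54e-05). This call also held with an estimated correlation (camera adjusted p = 0.0183). With each gene's own total count as the offset, the list members Zic2 and Sox4 turned below 0, as given above. No list was tested with that offset, so the list calls at 0 h are not shown to be separate from total RNA. Immediate early genes were lower, with 8 of 22 called and 9 over the list alone (median -1.03, adjusted p = 5.13e-05), among them Junb (-2.83, SE 0.50) and Spry2 (-2.31, SE 0.46). That call was lost at adjusted p = 0.520 with an estimated correlation. Endoderm markers were lower, with 5 of 16 called and 8 over the list alone (median -1.64, adjusted p = 0.00613). That call was lost at adjusted p = 0.520 with an estimated correlation. Pluripotency factors and G1/S genes were also called downward without the 2 shallow libraries (adjusted p = 0.0407 for both, against 0.442 and 0.198 in 14 libraries). With an estimated correlation in 14 libraries both lists were at camera adjusted p = 0.984.

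During the chase labelled RNA was lost from nearly every tested gene in both genotypes. It fell in 11587 of 12678 genes in WT and in 11181 in Mettl3-KO. The half-life of the median slope was 1.80 h in WT and 2.12 h in Mettl3-KO.

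The labelled share of whole libraries fell from 39.4% in WT and 26.3% in Mettl3-KO at 0 h to 4.12% ± 0.57 (SD, n = 2) and 4.93% ± 0.05 (SD, n = 2) at 8 h. Its slope was -0.343 log2 per hour (SE 0.102, n = 6) in WT and -0.317 (SE 0.0544, n = 8) in Mettl3-KO, a difference of 0.0259 that the exact permutation test did not call (p = 0.759 over 324 assignments). The shallow libraries had labelled shares of 8.43% (WT 1 h replicate 2) and 6.90% (Mettl3-KO 3 h replicate 2), against 30.8% and 18.5% in the other library of their group. Without both, the difference was 0.0983 (exact permutation p = 0.00926 over 108 assignments), and without WT 1 h replicate 2 alone it was 0.0983 (exact p = 0.00617).

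**Figure D3:**
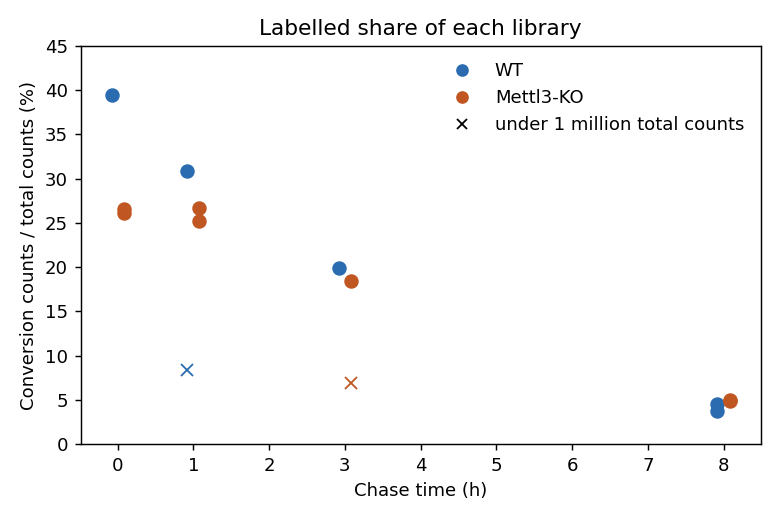
Conversion counts as a percentage of total counts in each library over chase time in hours (blue WT, orange Mettl3-KO; crosses are the 2 shallow libraries). The share falls from 39.4% to 4.52% and 3.72% in WT and from 26.1% and 26.6% to 4.90% and 4.97% in Mettl3-KO.

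The loss of labelled RNA was slower in Mettl3-KO for 304 genes and faster for 26 of 12678 tested, with a median difference of 0.0968 log2 per hour and 68.8% of genes above 0. The median was 0.0123 with TMM on the conversion counts, 0.0486 in the 1 h and 8 h libraries alone and 0.175 by limma on the authors' deposited normalized values. The genes with the smallest p among the slower ones were Timm8b, Nme6, Vamp3, Ndc80, 0610010K14Rik, Gm21988, Fuca1 and Bmyc. Timm8b, a mitochondrial import chaperone, differed by 0.72 (SE 0.12, edgeR adjusted p = 0.000313), with half-lives of 1.17 h in WT and 7.21 h in Mettl3-KO. Bmyc, a MYC family gene, differed by 0.72 (SE 0.14), with 0.997 h and 3.56 h, and did not pass without WT 8 h replicate 1. 0610010K14Rik and Gm21988 carry identical conversion counts and count as 1 signal. The faster genes were led by Nusap1, Avl9, Rsad1, Jmjd7, Fam149a, Snora20, Ikzf2 and Gm45902. Nusap1, a spindle protein, differed by -0.58 (SE 0.12).

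Genes such as Nme6, Vamp3, Ndc80 and Fuca1 still had labelled shares of 35%, 38.5%, 40.7% and 49.7% at 8 h in Mettl3-KO. In WT those were 0.88%, 3.18%, 1.00% and 0.57%. Nusap1 had 53.3% in WT and 1.14% in Mettl3-KO at 8 h. Its WT share at 0 h was 51.7%, so no loss of label shows for it in WT. Among 8745 genes with at least 200 total counts at 8 h in each genotype, 25 had over 20% at 8 h in Mettl3-KO and under 5% in WT, and 14 the reverse. Of the 25, Gm45837 and Pde2a carry identical values and count as 1 signal. A loss rate difference was called for 18 of the 25 and 6 of the 14. Conversions that do not depend on the label may explain the Mettl3-KO set, as weighed below. Calls for genes with such shares may therefore not measure stability. Without genes above 20% at 8 h in either genotype 256 were slower and 17 faster.

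Nuclear-encoded oxidative phosphorylation genes lost label more slowly in Mettl3-KO as a group, with a median difference of 0.225 log2 per hour. Of 65 measured 64 lay above 0, 7 were called and 26 were when adjusted over the list alone. Uqcrq, of respiratory complex III, differed by 0.43 (SE 0.11), Ndufb3, of complex I, by 0.42 (SE 0.11), Uqcr10 by 0.39 (SE 0.10) and Atp5g3, of ATP synthase, by 0.39 (SE 0.11). The camera adjusted p was 8.30e-12 with the preset correlation, and the call was lost at adjusted p = 0.850 with an estimated correlation. Their labelled RNA at 0 h had a median difference of -0.54 (camera adjusted p = 0.109, and 0.0183 without the 2 shallow libraries). With an estimated correlation in 14 libraries the camera adjusted p at 0 h was 0.984. Both differences come from the same fit, so a low start and a slow loss are not separate measurements. Of 74 ribosomal proteins 1, Rpl29, was slower (0 over the list alone).

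No difference in the loss rate of Mycn was detected in the counts, at 0.003 log2 per hour (SE 0.09), with half-lives of 1.55 h in both genotypes. Myc stood at -0.13 (SE 0.19), Nanog at -0.01 (SE 0.10), Sox2 at -0.14 (SE 0.10), Klf4 at 0.20 (SE 0.10) and Pou5f1 at 0.20 (SE 0.12), and none passed. The list of mRNAs described as m6A-methylated had 0 of 13 genes called by edgeR and 0 over the list alone, with a median of -0.01. In simulated counts 5% of genes changed by 0.25 log2 per hour were recovered. The lack of calls for single genes here therefore does not exclude differences of that size. At an unadjusted p under 0.05 there were 2369 genes among all tested, and no list other than oxidative phosphorylation had a camera call for the loss rate in all 14 libraries. Zfp genes were called downward without the 2 shallow libraries (adjusted p = 0.0268, against 0.0762 in 14 libraries and adjusted p = 0.850 with an estimated correlation).

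The count of slower genes depended on single libraries and on the processing. It was 60 without WT 8 h replicate 2, 91 without Mettl3-KO 8 h replicate 2, 98 without WT 8 h replicate 1, 126 without Mettl3-KO 8 h replicate 1, 137 without Mettl3-KO 0 h replicate 1, 147 without WT 1 h replicate 1 and 188 without Mettl3-KO 1 h replicate 1. It was 473 without Mettl3-KO 3 h replicate 2, 514 without WT 3 h replicate 1 and 640 without both shallow libraries. The count of faster genes was 68 without WT 0 h replicate 1, 43 without WT 3 h replicate 1 and 41 without Mettl3-KO 3 h replicate 2. It was 12 without Mettl3-KO 0 h replicate 1, 13 without WT 1 h replicate 1, 16 and 17 without Mettl3-KO 1 h replicate 1 and replicate 2, 8 without WT 8 h replicate 2, 13 without Mettl3-KO 8 h replicate 1 and 2 (Nusap1 and Gm49957) without Mettl3-KO 8 h replicate 2. DESeq2 called 684 slower genes, the total count without TMM as the library scale gave 141, own TMM scaling gave 186 slower and 120 faster (60.8% slower against 92.1%) and 8 h against 0 h gave 89 slower and 4 faster (Nusap1, Gm2522, Avl9 and Snord3a). Genes named here for these small counts were chosen after their values were seen. Of 100 assignments of genotype within chase time, 6 including the real one called as many genes, so chance was not excluded.

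In the authors' deposited table the median half-life was 1.69 h in WT and 2.52 h in Mettl3-KO over 6985 genes, with Mettl3-KO above WT for 83.4%. Fitted here from the counts over the 6980 shared genes, the medians were 1.71 h and 1.88 h, with 65.7% above. Mycn had half-lives of 1.54 h in WT and 2.66 h in Mettl3-KO in the authors' deposited table.

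The authors' deposited normalized values are log2 values of the conversion counts in 10 libraries. In the other 4 they are log2 values of a multiple of the counts, by a factor of 1.2 in both Mettl3-KO 0 h libraries, 2.34 in Mettl3-KO 8 h replicate 1 and 1.625 in Mettl3-KO 8 h replicate 2. At least 94.5% of genes lay within 1% of these factors. For Mycn the deposited value was 2.00 times the library's factor in Mettl3-KO 3 h replicate 1, 3.05 times in Mettl3-KO 8 h replicate 1 and 2.00 times in Mettl3-KO 8 h replicate 2. Of 74700 values with at least 50 counts, 5 lay over 1.5 times from their library's factor: these 3 of Mycn, and 1 each of Alg3 (0.66) and Crispld1 (1.59). The reason for the factors is not given in the sources used here. limma on the deposited values called 1073 slower and 14 faster genes, and on values remade from the counts without the library factors 171 and 8.

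**Figure D4:**
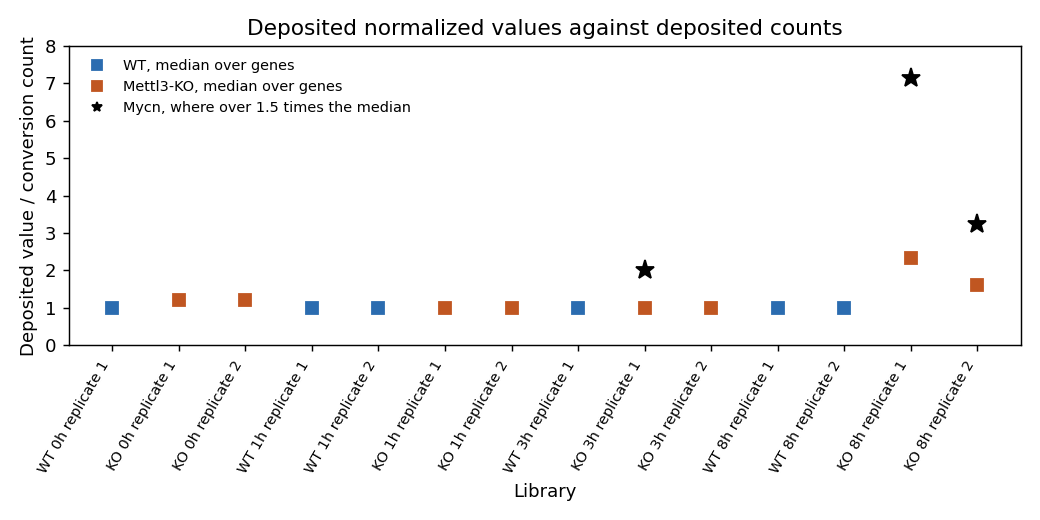
Deposited normalized value, with each library's own scale taken out, divided by the deposited conversion count, for each library (squares, median over genes; blue WT, orange Mettl3-KO) and for Mycn where it lies over 1.5 times from the median (stars). The squares lie at 1 in 10 libraries and at 1.2, 1.2, 2.34 and 1.625 in the Mettl3-KO 0 h and 8 h libraries.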

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

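Tests chosen after the result was seen are those of long-lived RNA, of label-independent conversions, of the makeup of WT 1 h replicate 2, of mixing as the cause of both low shares and of the Mycn multiples. Verdicts on the neighbour tests, on label-independent conversions in WT and on long-lived RNA in both genotypes were also set after their values were seen, and all were left open. Of 56 groups of 6 or 8 libraries checked, 15 had 1 library far from the others, where chance gives about 1 in 20.

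Most of these lie in the 2 shallow libraries. In WT 1 h replicate 2 these were Mycn (263.8 CPM, others 76.5 to 109.7), Igfbp2 (40.59), Zic5 (60.88, others at most 11.2), Rragd (40.59) and Islr2 (20.29, others at least 91.5), with Fmr1nb, Wnt6 and Msln listed at 0. A single count is 20.3 CPM in that library, so a 0 or a level of 1 or 2 counts there decides little. In Mettl3-KO 3 h replicate 2 they were Mettl3 (5.593 CPM, 2 counts), Sult5a1 (2.796), Islr2 (13.98) and the TMM factor (0.5937, others at least 0.993). The rest were Pou5f1 in Mettl3-KO 1 h replicate 2 (93.33), Cyyr1 in WT 3 h replicate 1 (0.1739) and Emp2 in WT 8 h replicate 1 (58.4).

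The first pattern weighed is the makeup of the 2 shallow libraries, which hold 49159 and 602485 total counts and have low labelled shares. In WT 1 h replicate 2, genes near absent from WT stood at 50.05% of their Mettl3-KO level (33.3 to 72.3, 7 genes, 28 counts) and WT-only genes at 18.81% of the WT level (15.2 to 23.0), which argues against an unmixed library of the other genotype, while in Mettl3-KO 3 h replicate 2 WT-only genes stood at 11.09% of their WT level (10.0 to 12.2) and Mettl3-KO-only genes at 92.6%. Reads of the other genotype may explain these levels in part, and no biological explanation was tested. Such reads cannot explain Meg3, at 325 CPM (16 counts) in WT 1 h replicate 2 and 464 CPM (166 counts) in Mettl3-KO 3 h replicate 2. Deep libraries of either genotype held at most 11.8 CPM of Meg3. A mix of the 2 genotypes alone therefore does not account for the makeup of these libraries. For the low labelled shares, reads of the other genotype could leave no less than 16.05% in Mettl3-KO 3 h replicate 2, where 6.90% was seen. This argues against such reads as the whole cause there. In WT 1 h replicate 2 they could leave no less than 8.847%, where 8.43% was seen (95% interval up to 8.68%). This goes against such reads as the whole cause but by less than the 1.5 times set for the test, so it stays open. Mixing with libraries of the same genotype at other chase times was not tested. Genes over 3 times their highest level in the deep libraries, many at single counts, hold 41% and 48.5% of the counts of the 2 libraries, and without them the share was 42.92% of that of WT 1 h replicate 1, which argues against them as the whole cause, and 11.2% against 18.5% in the Mettl3-KO library.

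The second pattern is a high labelled share after 8 h in 1 genotype alone, for 25 genes in Mettl3-KO (such as Fuca1, Nme6 and Vamp3) and 14 in WT (such as Nusap1). Long-lived RNA was predicted to have taken up little label in 12 h. The median share of the WT set at 0 h was at the 90.04 percentile of tested genes, and its share at 8 h sets a floor at the 12.3 percentile. That floor assumes no loss of label, and with any loss a high share at 8 h needs a still higher share at 0 h. The medians of the WT set were 58.2% at 0 h and 32.2% at 8 h. The choice of genes thus favoured a high percentile, so the test cannot decide on long-lived RNA in WT. In Mettl3-KO the set was at the 96.43 percentile, but with a floor at 43.3 a low percentile was ruled out by the choice of genes. Long-lived RNA therefore stays open in both genotypes. Conversions that do not depend on the label may explain the set in Mettl3-KO, where a fixed share read off at 8 h, joined to the WT share at 0 h scaled to Mettl3-KO, missed the share at 0 h by a median of 4.804 points (14.8 without the fixed share). In WT the miss was 8.374 points with it and 9.67 without, so the test decides nothing. Sequence variants of either line, which would be a form of such conversions, stay open. Random gene sets had as many neighbours within 1 Mb in a share of 0.384 (Mettl3-KO) and 0.136 (WT) of draws. Isolated variants need not lie near each other, and wider windows were not tested.

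The last pattern is the half-life of Mycn, longer in Mettl3-KO from the authors' deposited normalized values (2.63 h against 1.46 h in WT) and alike in the fit of the counts. With the library multiples alone, the difference was 30.3% of that from the deposited values, and with the deposited counts without any multiple it was 5.53%. The multiples in the deposited table may therefore account for most of the difference. Their reason is not given in the sources used here, so whether they correct something that the counts do not show stays open.

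A difference between the groups over time was seen in 330 genes, whose loss of labelled RNA differed between WT and Mettl3-KO by the interaction test. Of 100 drawn assignments of genotype within chase time (of 324), 6 including the real one called as many, so chance is not excluded. The highest other called 1288, several times the real count. Regrouped libraries keep their genotype difference in total RNA, so the assignments are not a clean null for the loss rate. Without the 2 shallow libraries 678 genes were called, 3 of 100 drawn assignments (of 108), the real one included, called as many and the highest other called 1485. That share lies under 0.05, but the fit was chosen after the data were seen. Its assignments have the same limit, so chance is not excluded there either.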

How the results depend on the processing

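Chosen after the data were seen were the fits without the 2 shallow libraries, without genes of high labelled share at 8 h or with more conversion than total counts and on the authors' normalized values. So was the replicate block for the gene lists. The 2 shallow libraries limit what the 14 libraries can show, and where no cause is given below, the cause was not tested.

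For total RNA, higher and lower genes (1769 and 1462) became 1097 and 973 with no filter, 3189 and 2812 without the 2 shallow libraries, and 2358 lower by DESeq2. Leaving out 1 library gave 1206 to 2800 higher and 953 to 2481 lower. The time trend (0 genes by edgeR, 728 at an unadjusted p under 0.05) gave 197 by DESeq2, 80 without the 2 shallow libraries and 0 to 17 without 1 library.

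For labelled RNA at 0 h, higher and lower genes (171 and 795) became 385 and 491 with TMM on the conversion counts, 0 and 1 (Dido1) with each gene's total count as offset, 585 and 1483 in the 0 h and 1 h libraries, and 465 and 1721 in those without the shallow one. A stricter filter gave 108 higher, the replicate block 466 lower (the numbers do not pair the samples), and leaving out 1 library 77 to 211 and 312 to 989. Values turned with each gene's total count as offset, which takes out the change in total RNA, for Mycn (-0.27), Stmn2 (-0.41), Zic5 (-0.12), Ythdf2 (-0.047), Zic2 (-0.13), Sox4 (-0.30), Ccnd2 (-0.25), Rragd (-0.45) and Tubb3 (-0.92).

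For the loss rate, slower and faster genes (304 and 26) became 141 and 17 with total counts without TMM, 186 and 120 with TMM on the conversion counts, 684 and 44 by DESeq2, 89 and 4 (Nusap1, Gm2522, Avl9 and Snord3a, chosen after their values were seen) for 8 h against 0 h, 1073 and 14 by limma on the authors' deposited normalized values and 171 and 8 on values remade without their factors. There were 102 slower in the 1 h and 8 h libraries, 640 without the 2 shallow libraries, 589 also without genes of high share at 8 h, and 17 faster without those genes alone. Leaving out 1 library gave 60 to 514 and 2 to 68. Without 1 library Zfp981 ranged from -0.34 (without WT 0 h replicate 1) to 3.06 and Zfp109 from -1.74 to 0.073 (without WT 8 h replicate 1).

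Genes with falling label (11587 in WT, 11181 in Mettl3-KO) became 318 and 1168 with TMM on the conversion counts, which by construction removes a loss shared by all genes. Without 1 library they were 10330 to 11640 and 9666 to 11318. The difference in slope of the library-wide share (0.0259) was -0.206 without the 8 h libraries, 0.0744 as the median over genes, 0.0391 over filtered genes, 0.0051 with the replicate block, 0.0983 without the 2 shallow libraries and -0.0142 to 0.0983 without 1 library. Lists called for total RNA, labelled RNA at 0 h and the loss rate (4, 3 and 1) were 0, 1 and 0 with an estimated correlation, 9, 6 and 2 without the 2 shallow libraries, and 5, 3 and 1 with the replicate block. That block adds MYC target genes upward for total RNA (camera adjusted p = 0.0283). Without the block and with an estimated correlation that list was at adjusted p = 0.778.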

Other observations

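Tests chosen after the result was seen are those of depth and of Y loss for the Y-linked genes. The verdicts on Y loss, on whole chromosomes and on slower loss as a source of higher total RNA were set after their values were seen, and all 3 were left open.

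For total RNA 1 of 100 drawn assignments of genotype within chase time (of 324), the real one, called as many genes as the 3231 of the real groups, with 1427 in the highest other. For labelled RNA at 0 h it was 2 of 100, with 966 genes in the real groups and 1441 in the highest other. Both shares lie under 0.05. For total RNA this shows that the libraries differ by their genotype label. Since replicates may be technical, it does not exclude a chance difference between the cultures. For labelled RNA at 0 h another assignment called more genes than the real groups. Regrouped libraries keep their genotype difference in total RNA, so the assignments are not a clean null for either test. Chance is left open for labelled RNA at 0 h.

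Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y stood at 0.858%, 0.838%, 0.866% and 1.13% of the Mettl3-KO level in the deep WT libraries. Lower depth of WT is argued against, since at the Mettl3-KO level the least covered of these genes would have had 51.58 counts in a deep WT library. Loss of the Y chromosome from most cells of the WT line is a candidate explanation that stays open, since Gm17790, on the same chromosome, stood at 84.78% of its Mettl3-KO level but near the floor (1.04 and 1.22 CPM).

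By chromosome, the median change of total RNA lay farthest from that of all genes on chromosome 8, at -0.2672 (bootstrap interval -0.332 to -0.199). Loss of a whole chromosome 8 in some cells of the Mettl3-KO line, or its gain in some cells of the WT line, could give such a shift. Both stay open because the interval spans the bound of 0.3 set for the test. Chromosome 1 stood at -0.203 and the X chromosome at 0.199 from the median of all genes.

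If slower loss raised total RNA, the 2 changes would go together across genes. Pearson r was 0.028068, inside the range of the other assignments (-0.502 to 0.483). No link was detected, and with so wide a range this does not exclude one, so the bound set beforehand, any r inside that range, was wrong.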
